A study of Mus musculus with 12 samples.

How the data were processed

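RNA was measured in C2C12 cells, a mouse skeletal muscle line that the sample titles name as myoblasts. Per the labels' protocols, dishes that had reached 100% confluency received perfluorooctanesulfonate (PFOS, a persistent perfluorinated surfactant) at 0, 2 or 6 µM for 24 h. RNA was extracted with TRIzol, messenger RNA was purified from it, and a service company built the libraries. Each dose had 4 libraries, 12 in all, and each library was assigned to its dose from its sample title. Nothing in the labels says that the 4 libraries of a dose came from separate cultures, so p-values here measure only the spread between these samples, which may be technical.

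The authors deposited 1 table of whole-number read counts per gene, not normalized, for 54532 genes. Per the submitters' processing notes, reads were aligned with HISAT2 and the genome build was GRCm39. The version of the aligner, the counting program and its strand setting, the annotation release and any read filter are not given in the sources used here. The gene coordinates in the deposited table are not those of GRCm39: of 54495 genes that the table shares with GENCODE release M21, 53585 (98.3%) have the same chromosome, start and end as in that annotation, which is on GRCm38. Coordinates are therefore given as the table lists them and named as GRCm38. Without a stated strand setting, reads of overlapping or antisense genes may not be told apart, and genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, are uncertain.

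The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM factors, genes were filtered by edgeR's filterByExpr with dose as the group, and edgeR's quasi-likelihood test was run on 1 model with a mean per dose over all 12 libraries, which leaves 9 residual degrees of freedom. The filter kept 16038 genes and left out 38494. The tests compared 2 with 0, 6 with 0 and 6 with 2 µM. The last is the direct test of the difference between the doses. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no limit on its size. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the F statistic. Counts-per-million values (CPM) were computed from the deposited counts with TMM-scaled library sizes. They are given as mean ± SD over the 4 libraries of a dose. The common biological coefficient of variation was 10.8%.

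Before the data were examined, 40 gene lists were written from textbook knowledge. They cover lipid and energy metabolism, mitochondria, stress responses, muscle genes, growth, extracellular matrix, signalling, quality checks and markers of other cell types. The lists share members, so calls of different lists are not independent. For example, Cpt1a and Acadl are in both the PPAR target and the fatty acid oxidation list. Hk2 and Slc2a1 are in the glycolysis, insulin and hypoxia lists. Members were matched by exact symbol. Aldoa stands for 2 genes in the table, so the 23 glycolysis symbols gave 24 tested genes, and Ccn1 and Ccn2, which the table lists under older symbols, were not matched in the extracellular matrix and TGF-beta lists. The 37 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided. Camera asks whether a list's genes moved relative to the other genes. Its p-values were adjusted over 111 tests, the 37 lists in each of the 3 comparisons. Camera was also run with the correlation estimated from the data for each list. Members called were counted with adjustment over all tested genes and also adjusted over the list alone.

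The genes named in the text follow a rule that was also fixed before the data were examined. The rule starts from called genes that have a symbol, a mean log2 CPM of at least 1 and no overlap between the CPM of the compared doses. Symbols that start with Gm and a digit or end in Rik, and pseudogenes, are left out there. Of the rest, the rule takes the 10 with the largest change in each direction for 6 against 0 µM and the 5 for the other comparisons. It adds up to 2 called members of each list with the smallest adjusted p. Ppara, Ppard, Pparg, Myod1 and Myog are given whatever their p. After the values were seen, a call of a rule gene that ended in 3 or more of the fits without a single library was left out of the account of that comparison, except for Pparg, Ndufb11 and the genes that turned between the doses. Such genes still appear where another comparison or a library far from the others is described. Genes named outside the rule are said to be so.

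The steps were tested on simulated counts drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed at each of 2 and 6 µM. For the simulated 2 against 0 µM comparison, run on 15679 genes, 47.7% of genes changed 1.25-fold, 61.5% of those changed 1.5-fold and 63.1% of those changed 2-fold were called, with 6.7% false calls. For the simulated 6 against 0 µM comparison, on the same number of genes, these were 42.9%, 68.7% and 72.3%, with 3.2% false calls. In these simulations many changes, also of 2-fold, were missed. Changed genes were drawn at random, whatever their abundance. The simulated comparisons had 120 and 124 called genes, against 377 and 1322 in the data. The Benjamini-Hochberg limit was therefore stricter there, and the shares found need not hold for the data. In a separate simulation on 15681 genes, camera called a list of 30 genes raised 1.2-fold at 6 µM and 0 of 40 unchanged lists. Genes were drawn independently there and the unchanged lists at random. That simulation therefore cannot show how often camera makes false calls for lists whose genes are correlated.

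Total counts per library ran from 30206155 to 50351082. A count of 3, the limit that a count of 0 allows, corresponds to 0.0596 to 0.0993 CPM. Such floors cover counting error only. The deposited counts matched 12 samples by title.

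Alternatives fixed before the data were examined were median-ratio and upper-quartile scaling, no count filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, a fit of only the compared groups, the replicate number as a block, removal of gene length and GC trends with and without that block, mitochondrially encoded genes left out, an adjusted p under 0.01, a fold change of at least 1.5, camera with an estimated correlation, fry, control libraries divided between the comparisons, and each library left out in turn. Leaving out the 3 libraries that deviated most from the mean of their dose (0 µM replicate 1 and 6 µM replicates 2 and 3) was chosen after seeing the data. Library measures at equal depth were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.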

Results

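Messenger RNA was measured by RNA sequencing in C2C12 myoblasts, with 4 libraries at each of 0, 2 and 6 µM PFOS. Total gene counts averaged 36.8 ± 7.09 M at 0 µM, 44.4 ± 4.66 M at 2 µM and 43.1 ± 2.22 M at 6 µM (SD, n = 4), and ranged from 30206155 to 50351082 over the 12 libraries. Between 19292 and 21171 genes had counts in a library, and protein-coding genes took 96.74% to 97.05% of the counts. Mitochondrially encoded genes took 1.87% to 2.57%, and the 10 most abundant genes took 5.6% to 5.91%. The series title concerns metabolism in this cell line, and the 3 comparisons ask which genes differed at each dose from no PFOS and between the doses.

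Genes changed at both doses, and more of them at 6 µM. By edgeR's quasi-likelihood test, 258 of 16038 genes rose and 119 fell at 2 µM against 0 µM. At 6 µM against 0 µM, 735 genes rose and 587 fell, while with upper-quartile scaling 598 rose and 662 fell, so which direction had more genes depended on the scaling. At 6 µM against 2 µM, 90 genes rose and 88 fell. Most changes were small. The median called gene at 6 µM against 0 µM rose 1.17-fold or fell 1.29-fold, and 21 genes rose and 57 fell at least 2-fold. On the principal component axes of log2 CPM, the leading axis held 15% of the variance and the next 11.3%. The libraries of 0 µM replicate 1 and 6 µM replicates 2 and 3 deviated most from the mean of their dose, by 0.402, 0.424 and 0.422 (root mean square, log2 scale). Without these 3 libraries, 408 genes rose and 302 fell at 6 µM against 0 µM, 302 rose and 159 fell at 2 µM against 0 µM, and 81 rose and 55 fell at 6 µM against 2 µM.

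**Figure D1:**
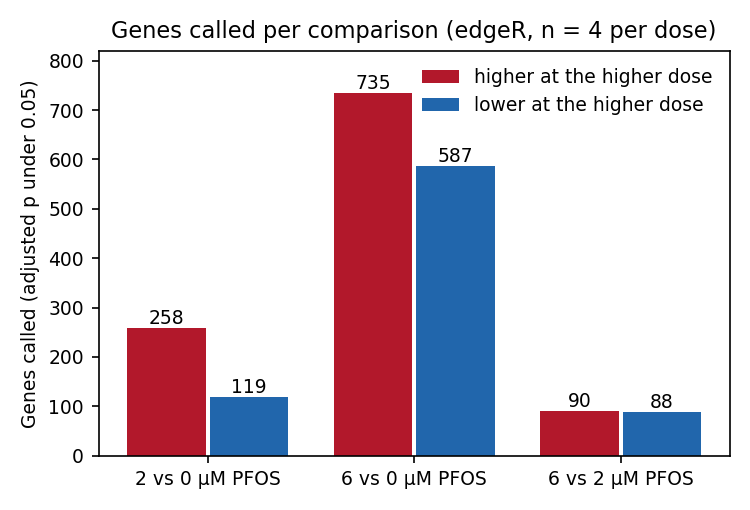
Number of genes called higher and lower in each comparison of PFOS doses, at an adjusted p under 0.05 by edgeR's quasi-likelihood test over 16038 genes (n = 4 libraries per dose). The comparison of 6 with 0 µM has the most calls, 735 higher and 587 lower, against 598 higher and 662 lower with upper-quartile scaling.

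The comparison of 2 with 0 µM asked what the lower dose changed. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, rose 6.56-fold, from 9.42 ± 1.02 to 61.7 ± 2.94 CPM (mean ± SD, n = 4). Its log2 fold change was 2.72 with an SE of 0.0688, and its adjusted p was 1.73e-17 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Angptl4 (ENSMUSG00000002289) is a protein-coding gene on the minus strand of chromosome 17 from 33773750 to 33781575 (GRCm38). Cpt1a, whose product controls the entry of fatty acids into mitochondria, rose 1.44-fold, from 86.0 ± 4.596 to 124.1 ± 3.60 CPM. As groups, PPAR target, integrated stress response, hypoxia and immediate early genes were higher and sarcomere genes lower by camera. With an estimated correlation the PPAR call held (adjusted p = 0.0177 by camera), and the others did not (adjusted p = 0.089, 0.202, 0.0897 and 0.0897 in that order). Dnah6, a dynein heavy chain gene, rose 3.21-fold, from 0.890 ± 0.138 to 2.89 ± 0.528 CPM. Efna3, which encodes an ephrin ligand, fell 1.9-fold, from 5.05 ± 1.06 to 2.67 ± 0.348 CPM, and Padi2, which encodes a peptidylarginine deiminase, fell 1.68-fold. Acsbg1, an acyl-CoA synthetase gene, rose 1.77-fold, but its adjusted p was 0.0731 without 2 µM replicate 4. Gdpgp1 fell 2.08-fold, with adjusted p values of 0.0688 without 0 µM replicate 3 and 0.0731 without 2 µM replicate 4.

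Of the 37 lists tested, camera called 9 higher and 3 lower at 2 µM against 0 µM. Of the 16 measured PPAR target genes, 7 rose, the others did not pass, and 9 were higher and 2 lower adjusted over the list alone. The list had a median log2 fold change of 0.26 and an adjusted p of 2.91e-08 by camera, and adjusted p = 0.0177 with an estimated correlation. It was the only list whose call held with an estimated correlation, in this and in both other comparisons. Of 35 genes of the integrated stress response (ATF4 targets), 19 rose and 29 were higher adjusted over the list alone, with a median of 0.17, an adjusted p of 1.75e-20 by camera and adjusted p = 0.089 with an estimated correlation. Among them Ppp1r15a, which encodes a subunit of an eIF2α phosphatase, rose 1.72-fold from 36.5 to 62.8 CPM, and the transcription factor gene Atf3 rose 1.74-fold from 25.1 to 43.7 CPM. Of 28 hypoxia genes, 5 rose, and 16 were higher and 1 lower adjusted over the list alone (camera adjusted p = 5.87e-07, and adjusted p = 0.202 with an estimated correlation). Ero1l, which encodes an oxidase of the endoplasmic reticulum, rose 1.37-fold, from 1997 to 2744 CPM. Of 27 immediate early genes, 8 rose and 9 were higher adjusted over the list alone (camera adjusted p = 1.03e-05, and adjusted p = 0.0897 with an estimated correlation), among them Myc at 1.32-fold. Of 25 inflammatory genes, 4 rose, the same number as adjusted over the list alone, and Ptgs2 rose 1.48-fold (camera adjusted p = 0.00873, and adjusted p = 0.0752 with an estimated correlation).

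At 2 µM against 0 µM, of 24 fatty acid oxidation genes, 2 rose and 3 were higher adjusted over the list alone (camera adjusted p = 0.00692, and adjusted p = 0.17 with an estimated correlation). Of 21 genes of fatty acid and triglyceride synthesis, 1 rose and 3 were higher adjusted over the list alone. Its camera adjusted p was 0.00574, 0.117 without 0 µM replicate 1, and adjusted p = 0.288 with an estimated correlation. Dgat2, which encodes an enzyme of triglyceride synthesis, rose 1.42-fold with an adjusted p of 0.0529 without 2 µM replicate 4 by edgeR's test. Of 24 glycolysis genes, 5 rose, and 8 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0127). That p was 0.292 without 0 µM replicate 1, and adjusted p = 0.561 with an estimated correlation. Pfkp, which encodes a phosphofructokinase, rose 1.12-fold, but its adjusted p by edgeR's test was 0.094 without 2 µM replicate 4 and 0.0801 with length and GC trends removed. Slc16a1, a lactate and pyruvate transporter gene, rose 1.15-fold. Of 27 insulin signalling and glucose handling genes, 3 rose and 5 were higher adjusted over the list alone (camera adjusted p = 0.0499, and adjusted p = 0.288 with an estimated correlation). The insulin list's camera adjusted p was 0.0951 and 0.183 without 0 µM replicates 1 and 2, 0.0936 and 0.0724 without 2 µM replicates 2 and 4, 0.0556 and 0.0527 without 6 µM replicates 1 and 4, and 0.0787 with upper-quartile scaling. It was 0.0526 with the replicate block.

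At 2 µM against 0 µM, of 33 sarcomere and contraction genes, 2 fell, and 9 were lower adjusted over the list alone, with a median log2 fold change of -0.20, an adjusted p of 9.18e-06 by camera and adjusted p = 0.0897 with an estimated correlation. Fewer genes also had at least 10 counts at 2 µM, as given with the library measures. Of 32 myogenic regulator and myoblast fusion genes, 2 fell, and 5 were lower adjusted over the list alone (camera adjusted p = 0.0231, and adjusted p = 0.398 with an estimated correlation). Dmpk, a muscle protein kinase gene, fell 1.35-fold, from 42.8 to 31.7 CPM. The camera adjusted p of the myogenic list was 0.0713 and 0.275 without 0 µM replicates 3 and 4, 0.0542, 0.054 and 0.0609 without 2 µM replicates 2, 3 and 4, and 0.1 with no count filter. Of 76 subunits of oxidative phosphorylation, none passed over all genes (0 of 76 by edgeR and 0 adjusted over the list alone), with 3 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 lower each. The median of these subunits was -0.05, with a camera adjusted p of 0.00692 and adjusted p = 0.637 with an estimated correlation. That call ended without 0 µM replicate 2 (0.454), without 2 µM replicate 3 (0.303) and with length and GC trends removed (0.232). The other 25 lists had adjusted p values from 0.0631 to 0.983 by camera, and 7 of them gained a call in some alternative that was tested with camera. Interferon response genes (0.0631) were called lower with the replicate block (0.0464). Ribosomal protein genes (0.101) were called higher with length and GC trends removed (6.94e-05), without 0 µM replicate 2 (3.37e-06) and without 2 µM replicate 3 (0.00117). Fibroblast markers (0.0676) were called lower at a mean count of at least 50 (0.0426), with the trends removed (0.0446) and without 2 µM replicate 3 (0.0435). Only without single libraries, muscle atrophy (0.08), extracellular matrix (0.236) and peroxisome genes (0.147) were called higher and antioxidant genes (0.155) lower. By fry, p53 target genes (0.186 by camera) were called higher (fry adjusted p = 0.0194). Interferon response and fibroblast genes were called lower by fry (0.00662 and 0.0201). The median, mean and test differed in sign for the TCA cycle, mitochondrially encoded, NRF2, lysosome, heat shock and histone lists.

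Single genes of other lists also changed at 2 µM. Sparc, an abundant extracellular matrix gene, fell 1.11-fold from 3895 to 3496 CPM. Inhba, which encodes an activin subunit, rose 1.37-fold. Atf6, a sensor of unfolded proteins, rose 1.19-fold, while Sdf2l1 of the endoplasmic reticulum fell 1.3-fold. Of the genes reported whatever their p, Ppara had a log2 fold change of 0.71 and an adjusted p of 0.697 at 0.247 CPM without PFOS, and Ppard had 0.09 and 0.612, both by edgeR's quasi-likelihood test. Pparg rose by 0.32 on the log2 scale with an adjusted p of 0.049 by the same test, and the call ended whichever of the 12 libraries was left out, with adjusted p values from 0.0506 to 0.15. Myod1 and Myog, which encode myogenic transcription factors, had log2 fold changes of -0.11 and -0.39 with adjusted p values of 0.579 and 0.225 by edgeR's test. Leaving out single libraries moved the 258 higher genes to 139 without 0 µM replicate 2, and to 157 and 72 without 2 µM replicates 2 and 4. It moved the 119 lower genes to 64, 56 and 73 without 0 µM replicates 2, 3 and 4, and to 56 and 34 without 2 µM replicates 2 and 4.

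The comparison of 6 with 0 µM asked what the higher dose changed. Angptl4 rose 21.5-fold, from 9.42 ± 1.02 to 201.6 ± 9.94 CPM (mean ± SD, n = 4), with a log2 fold change of 4.42, an SE of 0.0707 and an adjusted p of 8.54e-22 by edgeR's quasi-likelihood test. Pdk4, which encodes a kinase that inhibits pyruvate dehydrogenase, rose 2.7-fold, from 23.7 ± 0.892 to 63.9 ± 2.28 CPM. Cpt1a rose 1.97-fold, from 86.0 ± 4.596 to 169 ± 9.02 CPM. Of the genes of cholesterol synthesis 17 of 25 rose, while Acta2, the smooth muscle actin gene, fell 1.57-fold, from 447 ± 10.8 to 285 ± 8.62 CPM. Myog fell 1.76-fold, from 7.15 ± 1.249 to 4.06 ± 0.236 CPM. The Pdk4 gene (ENSMUSG00000019577, chromosome 6 from 5483351 to 5496309, minus strand), Cpt1a (ENSMUSG00000024900, chromosome 19 from 3323301 to 3385732, plus strand), Acta2 (ENSMUSG00000035783, chromosome 19 from 34241090 to 34255336, minus strand) and Myog (ENSMUSG00000026459, chromosome 1 from 134289989 to 134292548, plus strand) are protein coding, with positions on GRCm38. Their adjusted p values by edgeR's quasi-likelihood test were 3.84e-13, 1.12e-11, 1.59e-10 and 0.00172.

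**Figure D2:**
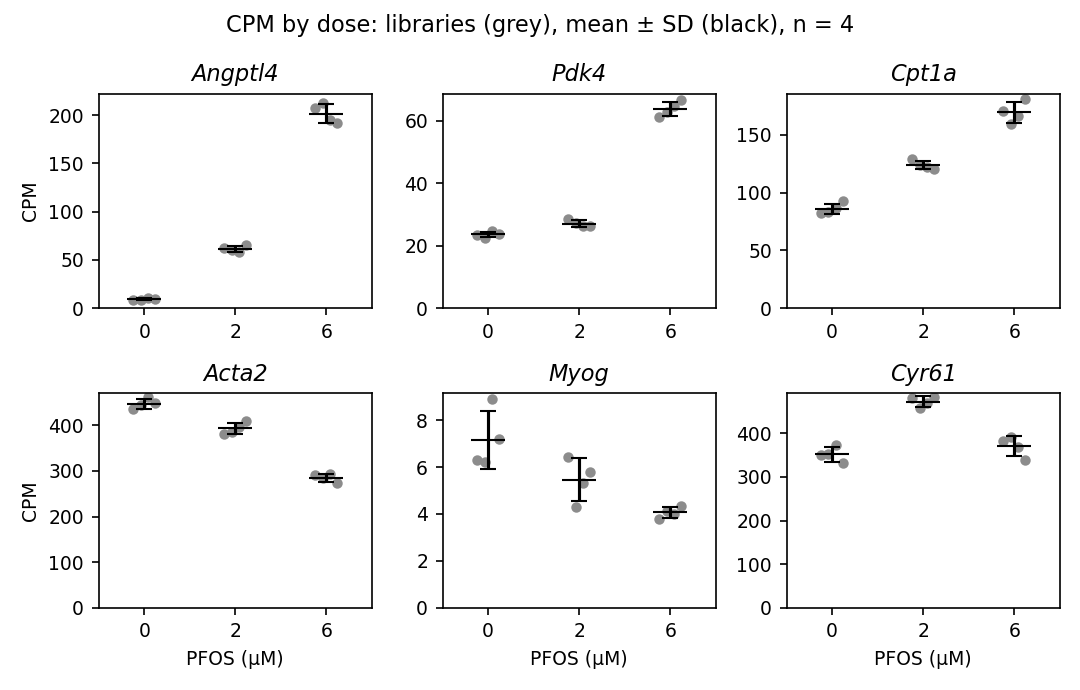
CPM of Angptl4, Pdk4, Cpt1a, Acta2, Myog and Cyr61 against PFOS dose in µM, with each library as a grey point and the mean ± SD of a dose in black (n = 4 libraries). Angptl4 averages 9.42, 61.7 and 201.6 CPM at 0, 2 and 6 µM, and Cyr61 is highest at 2 µM.

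Other genes with large increases at 6 µM were Dnah6 at 6.01-fold, Cyp26b1 at 3.81-fold, Acsbg1 at 2.71-fold, AU018091 at 2.67-fold and Slc25a34 at 2.55-fold. Cyp26b1, whose product breaks down retinoic acid, went from 2.24 to 8.56 CPM. Sprr1a rose 2.2-fold, Slc1a7 rose 2.11-fold and Fa2h, which encodes a fatty acid hydroxylase, rose 2.2-fold. The genes with large decreases were Aspn at 2.67-fold, Actc1 at 2.49-fold, Ces1d at 2.49-fold, Izumo4 and Clca2 at 2.3-fold, Aoc3 at 2.22-fold, P2rx6 at 2.19-fold, Padi2 at 1.98-fold, and Apobec2 and Zim1 at 1.95-fold. Actc1 is the cardiac actin gene, also expressed in early skeletal muscle, and Aoc3 encodes an amine oxidase whose mean went from 11.9 to 5.34 CPM. Without the 3 most deviating libraries, the adjusted p by edgeR's test was 0.177 for Fa2h, 0.0731 for Ces1d and 0.0613 for Izumo4.

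Of the 37 lists, camera called 14 higher and 3 lower at 6 µM against 0 µM. Of 16 PPAR target genes, 11 rose, and 11 were higher adjusted over the list alone, with a median log2 fold change of 0.55, a camera adjusted p of 1.31e-14 and adjusted p = 0.00269 with an estimated correlation. Of 25 cholesterol synthesis genes, 17 rose and 22 were higher adjusted over the list alone, with a median of 0.21, a camera adjusted p of 4.4e-14 and adjusted p = 0.0752 with an estimated correlation. Sqle, which encodes an enzyme early in the sterol branch, rose by 0.32 on the log2 scale, from 312 to 391 CPM. Of 21 genes of fatty acid and triglyceride synthesis, 13 rose and 14 were higher adjusted over the list alone (camera adjusted p = 6.31e-09, and adjusted p = 0.0752 with an estimated correlation). Scd1, which encodes a fatty acid desaturase, rose 1.27-fold from 780.2 to 989 CPM, and Acaca, which encodes acetyl-CoA carboxylase, rose 1.32-fold. Of 24 fatty acid oxidation genes, 8 rose and 1 fell, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.62e-05, and adjusted p = 0.0752 with an estimated correlation). Acadl, an acyl-CoA dehydrogenase gene that is also in the PPAR target list, rose 1.42-fold. Echs1, named after its values were seen, was the member that fell. Of the 15 adipocyte marker symbols, 7 were measured well enough to test, 4 rose (Lipe, Plin4, Pparg and Fabp4) and 5 were higher adjusted over the list alone (camera adjusted p = 0.000171, and adjusted p = 0.0752 with an estimated correlation). Lipe, which encodes hormone-sensitive lipase, rose 1.81-fold, and Plin4, a lipid droplet gene, rose 1.5-fold, while Fabp4, named after its values were seen, is also in the PPAR target list.

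At 6 µM against 0 µM, of 35 genes of the integrated stress response, 14 rose and 1 fell, and 23 were higher and 1 lower adjusted over the list alone (camera adjusted p = 5.36e-09, and adjusted p = 0.259 with an estimated correlation). Wars, which encodes tryptophanyl-tRNA synthetase, rose 1.34-fold and Aldh1l2, a mitochondrial folate gene, rose 1.28-fold, while Chac1, named after its values were seen, fell. Of 30 NRF2 target genes, 7 rose and 2 fell, and 15 were higher and 2 lower adjusted over the list alone (camera adjusted p = 6.12e-05, and adjusted p = 0.0897 with an estimated correlation). Among them Hmox1, the heme oxygenase gene, rose 1.31-fold and Pgd of the pentose phosphate pathway rose 1.21-fold. Of 28 hypoxia genes, 7 rose and 1 fell, and 13 were higher and 1 lower adjusted over the list alone (camera adjusted p = 2.84e-06, and adjusted p = 0.237 with an estimated correlation), with Ero1l at 1.44-fold, from 1997 to 2885 CPM. Of 27 immediate early genes, 9 rose and 12 were higher adjusted over the list alone (camera adjusted p = 0.000521, and adjusted p = 0.173 with an estimated correlation), with Fosl1 at 1.49-fold and Ier3 at 1.35-fold. Of 22 heat shock genes, 8 rose and 2 fell, and 10 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000805, and adjusted p = 0.202 with an estimated correlation). Hsp90ab1, a cytosolic chaperone gene, rose 1.15-fold from 3816 to 4401 CPM, and the mitochondrial chaperone gene Hspd1 rose 1.17-fold.

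Of 24 glycolysis genes, 8 rose and 11 were higher adjusted over the list alone (camera adjusted p = 0.000208, and adjusted p = 0.358 with an estimated correlation), and Slc16a1 rose 1.21-fold. Of 27 insulin signalling and glucose handling genes, 6 rose and 1 fell, and 9 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.018, 0.0735 without 0 µM replicate 2, and adjusted p = 0.245 with an estimated correlation). Slc2a1, which encodes a glucose transporter, rose 1.19-fold. Of 19 muscle atrophy genes, 4 rose (Mt1, Fbxo21, and, named after their values were seen, Psmd11 and Foxo1) and 5 were higher adjusted over the list alone (camera adjusted p = 0.000568, and adjusted p = 0.0752 with an estimated correlation). Mt1, a metallothionein gene, rose 1.26-fold and Fbxo21 rose by 0.32 on the log2 scale. Of 76 cytosolic ribosomal protein genes, 4 rose and 2 were higher adjusted over the list alone (camera adjusted p = 0.000208, and adjusted p = 0.612 with an estimated correlation). Rpl3 rose 1.1-fold, with adjusted p values by edgeR's test of 0.0519 and 0.0644 without 6 µM replicates 1 and 3. Rpl7a rose 1.57-fold with 0.0534 without 0 µM replicate 3, and its value is uncertain because it has pseudogene copies.

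At 6 µM against 0 µM, of 33 sarcomere and contraction genes, 13 fell and 20 were lower adjusted over the list alone, with a median log2 fold change of -0.60, a camera adjusted p of 1.02e-11 and adjusted p = 0.0516 with an estimated correlation. Myh1, a fast myosin heavy chain gene, fell 1.67-fold from 21.99 to 13.2 CPM, and Tnnt1, the slow troponin T gene, fell 1.94-fold from 12.3 to 6.32 CPM. Of 32 myogenic regulator and myoblast fusion genes, 2 rose and 12 fell, and 2 were higher and 14 lower adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.173 with an estimated correlation). Igfbp5, which encodes an IGF-binding protein, fell 1.32-fold from 1213 to 919.6 CPM. Myod1 fell 1.3-fold, from 30.3 to 23.2 CPM, with an adjusted p of 0.00333 by edgeR's quasi-likelihood test. In the same libraries, Gm26917, a noncoding gene on chromosome 17 that is known to overlap ribosomal RNA-like sequence and was chosen after its values were seen, rose by 0.52 on the log2 scale (adjusted p = 3.69e-05 by edgeR's test). Fewer genes were also detected at 6 µM, as given with the library measures. Of 76 subunits of oxidative phosphorylation, 3 fell and 1 was lower adjusted over the list alone, with a median of -0.06, a camera adjusted p of 0.017 and adjusted p = 0.671 with an estimated correlation. Of these 3, Uqcr11 fell 1.23-fold, Ndufb11 also fell, and Ndufa3 was named after its values were seen. The adjusted p of Ndufb11 by edgeR's test was 0.0998 without 0 µM replicate 2, and 0.081, 0.0642 and 0.0695 without 6 µM replicates 2, 3 and 4. The call of this list ended without 0 µM replicate 2 (0.454), without 6 µM replicates 2 and 4 (0.0724 and 0.0623), without the 3 most deviating libraries (0.105), with no count filter (0.0784) and with length and GC trends removed (0.186).

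**Figure D3:**
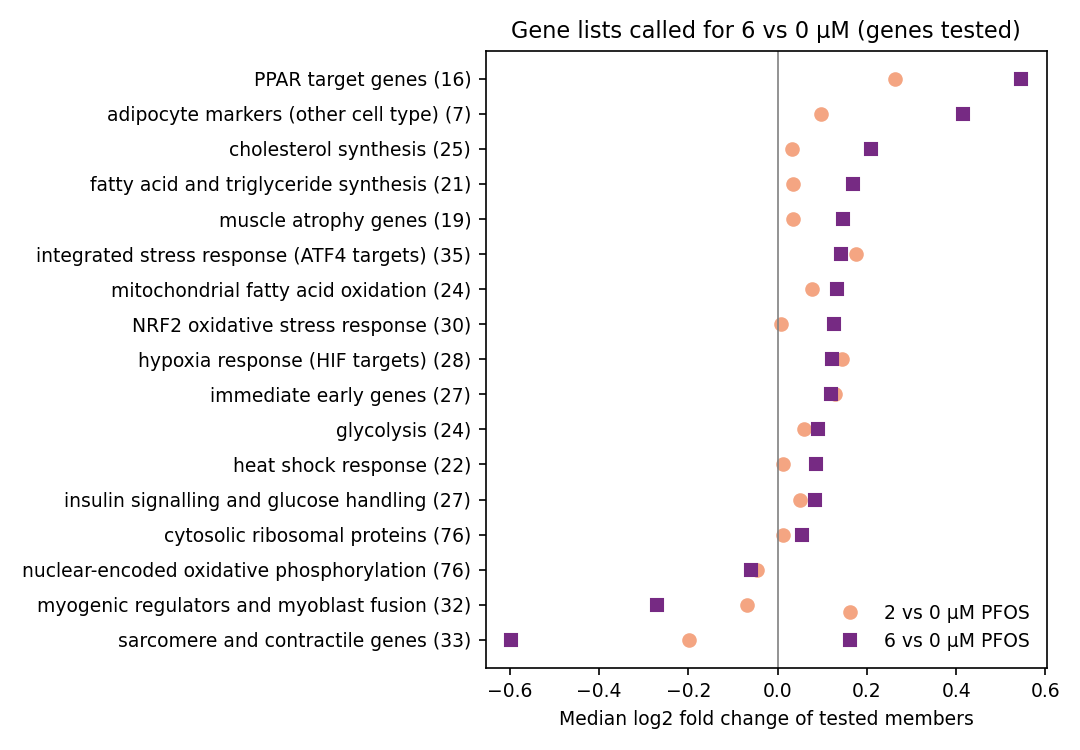
Median log2 fold change of the tested members of the 17 gene lists called by camera at 6 µM against 0 µM PFOS, with 2 µM against 0 µM as circles and 6 µM against 0 µM as squares. PPAR target genes have a median of 0.55 and sarcomere genes one of -0.60 at 6 µM.

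The other 20 lists tested were not called at 6 µM against 0 µM. Of 41 extracellular matrix genes, 9 rose and 9 fell, and 12 were higher and 13 lower adjusted over the list alone (camera adjusted p = 0.983). Postn, which encodes a matricellular protein, fell 1.41-fold. Of 22 TGF-beta and BMP genes, 3 rose and 5 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.211). Of 28 ion channel and calcium handling genes, 2 rose and 4 fell, and 4 were higher and 5 lower adjusted over the list alone (camera adjusted p = 0.546). Kcnj2, a potassium channel gene, fell 1.29-fold. Casq2, a calsequestrin gene, fell 2.69-fold, with an adjusted p by edgeR's test of 0.0509 without the 3 most deviating libraries. Of 31 peroxisome genes, 4 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.108), with Cat, the catalase gene, at 1.28-fold and Ech1, which encodes an enzyme for unsaturated fatty acids, at 1.55-fold. Of 28 p53 target genes, 3 rose and 6 were higher adjusted over the list alone (camera adjusted p = 0.0702), with Zmat3 at 1.24-fold and Aen at 1.22-fold. Of 48 cell cycle genes, 3 rose and 1 fell, and 6 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0577), with Rrm2, a ribonucleotide reductase gene, at 1.19-fold. Of 26 endoplasmic reticulum chaperone genes, 2 fell, and 3 were higher and 7 lower adjusted over the list alone (camera adjusted p = 0.142), with Sdf2l1 lower 1.51-fold. Of 17 xenobiotic genes, 3 rose and 1 fell, and 5 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.967), with Cyp1b1 at 1.36-fold and Tiparp at 1.24-fold.

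Of 36 lysosome and autophagy genes, 1 rose, as adjusted over the list alone (camera adjusted p = 0.0702), and this was Sqstm1 at 1.21-fold. Of 25 genes of mitochondrial biogenesis and dynamics, 2 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.209). Mief1 and Bnip3l are among them, and edgeR's adjusted p was 0.0642 and 0.0701 for Mief1 without 0 µM replicate 3 and 6 µM replicate 3, and 0.0592 for Bnip3l without 6 µM replicate 3. Of 31 TCA cycle genes, 1 rose and 1 fell, and 2 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.978), and Pdp1, a phosphatase gene of pyruvate dehydrogenase, was lower 1.28-fold. Of 22 antioxidant genes, 2 rose, and 2 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.983). Of 25 inflammatory genes, 2 rose, as adjusted over the list alone (camera adjusted p = 0.455), and they were Ptgs2 at 1.26-fold and Saa3, an acute phase gene, which went from 0.342 to 1.42 CPM. Of 24 interferon response genes, 1 rose, as adjusted over the list alone (camera adjusted p = 0.504), and this was H2-K1 at 1.18-fold. For the 13 mitochondrially encoded genes, edgeR, DESeq2 and limma-voom each called 0, also adjusted over the list alone for edgeR, with 2 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.776). For 77 mitochondrial ribosome genes, the same 3 tools called 0, with 6 higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.733). For 15 histone genes, they called 0, with 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.512). Of the 20 lists without a call, 5 gained one, each higher, in some alternative that was tested with camera. These were cell cycle genes with median-ratio scaling (0.0404) and in other settings, lysosome genes with no count filter (0.0201), and p53 target genes with no filter (0.0147) and with length and GC trends removed (0.0487). The others were peroxisome genes with no filter (0.0299) and mitochondrially encoded genes with the trends removed (0.0408). By fry, peroxisome, p53 target, lysosome and mitochondrial biogenesis genes were called higher (fry adjusted p = 0.0106, 0.00201, 0.0339 and 0.0413). Endoplasmic reticulum chaperone, TGF-beta and fibroblast genes were called lower by fry (0.0194, 0.00662 and 0.00662). The median, mean and test differed in sign for the TCA cycle, mitochondrially encoded, antioxidant, extracellular matrix, xenobiotic and histone lists.

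Markers of other cell types were checked in the same comparison. Of 6 osteoblast genes tested, 1 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.935), and Spp1, the osteopontin gene, rose 1.19-fold. Phex fell 1.7-fold, with an adjusted p by edgeR's test of 0.0666 without the 3 most deviating libraries. Of 9 fibroblast genes, 1 rose and 3 fell, as adjusted over the list alone (camera adjusted p = 0.169), with Col3a1 lower 1.21-fold and Pdgfrb lower 1.19-fold. Of 7 neuronal genes, 1 fell, and 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.586). Only 4 macrophage, 3 endothelial and 2 epithelial genes passed the count filter, too few for the list test. By edgeR, DESeq2 and limma-voom 0 of these were called, with 1 macrophage, 0 endothelial and 1 epithelial gene higher at an unadjusted p under 0.05. Of the genes reported whatever their p, Pparg rose 1.33-fold from 16.01 to 21.4 CPM, with an adjusted p of 0.00336 by edgeR's test. Ppara had a log2 fold change of 0.48 and an adjusted p of 0.74, and Ppard had 0.18 and 0.113, both by edgeR's test, while the call of Ppard was made without 0 µM replicate 4 (0.0464) and with no count filter (0.0199).

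The comparison of 6 with 2 µM is the direct test of the difference between the doses. Angptl4 rose a further 3.27-fold, from 61.7 ± 2.94 to 201.6 ± 9.94 CPM (mean ± SD, n = 4), with a log2 fold change of 1.71, an SE of 0.0596 and an adjusted p of 1.52e-14 by edgeR's quasi-likelihood test. Pdk4 rose 2.36-fold, from 27.1 ± 1.14 to 63.9 ± 2.28 CPM, and Cpt1a rose 1.37-fold. Cyp26b1 rose 2.23-fold and Slc25a34 rose 2.21-fold. AU018091 rose 2.66-fold, but its adjusted p by edgeR's test was 0.0744 without 6 µM replicate 4. Clca2 fell 2.04-fold, and Myl9, which encodes a regulatory myosin light chain, fell 1.8-fold from 8.92 to 4.96 CPM. Acta2 fell 1.38-fold, from 393.5 ± 12.1 to 285 ± 8.62 CPM.

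Camera called 11 lists higher and 4 lower at 6 µM against 2 µM. Of 16 PPAR target genes, 8 rose and 9 were higher adjusted over the list alone (camera adjusted p = 9.7e-16, and adjusted p = 0.00269 with an estimated correlation). Of 25 cholesterol genes, 10 rose and 19 were higher adjusted over the list alone (camera adjusted p = 3.08e-17, and adjusted p = 0.0752 with an estimated correlation), with Insig1, a sensor of sterols, at 1.23-fold and Hmgcs1, an enzyme of sterol synthesis, at 1.2-fold. Of 21 genes of fatty acid and triglyceride synthesis, 6 rose and 9 were higher adjusted over the list alone (camera adjusted p = 7.08e-07, and adjusted p = 0.0897 with an estimated correlation). Fasn, the fatty acid synthase gene, rose 1.33-fold, from 390.6 to 519 CPM, and Scd1 rose 1.19-fold. Of 24 fatty acid oxidation genes, 3 rose, and 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000208, and adjusted p = 0.0752 with an estimated correlation), with Acadl at 1.23-fold. Of 30 NRF2 target genes, 5 rose and 7 were higher adjusted over the list alone (camera adjusted p = 3.46e-08, and adjusted p = 0.0752 with an estimated correlation), with Pgd at 1.24-fold and Gstp1 at 1.26-fold. Of 22 heat shock genes, 3 rose and 9 were higher adjusted over the list alone (camera adjusted p = 8.15e-08, and adjusted p = 0.0752 with an estimated correlation), with Hsph1 at 1.28-fold. Of 7 adipocyte genes, 1 rose and 2 were higher adjusted over the list alone (camera adjusted p = 0.000899, and adjusted p = 0.0752 with an estimated correlation). Lipe rose 1.7-fold, with adjusted p values by edgeR's test of 0.0601 without 2 µM replicate 2 and 0.0636 without 6 µM replicate 4.

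Of 19 muscle atrophy genes, 1 rose and 3 were higher adjusted over the list alone (camera adjusted p = 0.0239, and adjusted p = 0.17 with an estimated correlation), and the call ended without 2 µM replicate 3 (0.0549) and without 6 µM replicate 3 (0.0825). Of 36 lysosome genes, edgeR called 0 and 2 were higher adjusted over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 2 higher each. Camera's adjusted p for lysosome genes was 0.0078, with 0.0592 without the 3 most deviating libraries and adjusted p = 0.17 with an estimated correlation. Of 24 glycolysis genes, edgeR called 0 and 2 were higher adjusted over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05, 2 higher by DESeq2 and 0 by limma-voom. The camera call of glycolysis (adjusted p = 0.0381, and adjusted p = 0.612 with an estimated correlation) ended without 2 µM replicate 3 (0.185), without 6 µM replicates 1 and 3 (0.0695 and 0.131) and with length and GC trends removed (0.197). Of 76 ribosomal protein genes, edgeR called 0, also adjusted over the list alone, with 3 higher at an unadjusted p under 0.05, 0 by DESeq2 and 1 higher by limma-voom. The camera call of ribosomal proteins (adjusted p = 0.00705, and adjusted p = 0.698 with an estimated correlation) ended without 2 µM replicate 3 (0.276) and without 6 µM replicate 1 (0.0556).

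Among the lists that were lower at 6 µM than at 2 µM, 22 TGF-beta and BMP genes had 1 that rose and 4 that fell, and 1 was higher and 9 lower adjusted over the list alone (camera adjusted p = 9.31e-05, and adjusted p = 0.0752 with an estimated correlation). Bmp4 fell 1.31-fold. Of 33 sarcomere genes, 1 fell and 4 were lower adjusted over the list alone, with a median of -0.27 (camera adjusted p = 1.06e-06, and adjusted p = 0.0752 with an estimated correlation). Of 32 myogenic genes, 2 fell and 4 were lower adjusted over the list alone, with Igfbp5 lower 1.19-fold (camera adjusted p = 0.00151, 0.0768 without the 3 most deviating libraries, and adjusted p = 0.259 with an estimated correlation). Gm26917 rose by 0.43 on the log2 scale in the same comparison. Of 35 genes of the integrated stress response, 2 fell, and 1 was higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0155, and adjusted p = 0.617 with an estimated correlation), a call that ended without 2 µM replicate 4 (0.21) and without 6 µM replicate 4 (0.25). Of 41 extracellular matrix genes, 1 rose and 5 fell, and 2 were higher and 8 lower adjusted over the list alone (camera adjusted p = 0.378), with Thbs1, the thrombospondin gene, lower 1.29-fold from 2198 to 1707 CPM and Postn lower 1.21-fold. The 22 lists without a call had camera adjusted p values from 0.0577 to 0.967. Antioxidant genes (0.0577) were called higher with no count filter (0.0397) and without 2 µM replicates 1 and 4 (0.0273 and 0.0443). Inflammatory genes (0.0702 by camera) were called lower by fry (fry adjusted p = 0.00662). The median, mean and test of the lists without a call differed in sign for peroxisome, TCA cycle, mitochondrial biogenesis and xenobiotic genes.

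Of the genes reported whatever their p, Ppara, Ppard and Pparg had log2 fold changes of -0.23, 0.09 and 0.09 at 6 µM against 2 µM, with adjusted p values of 0.932, 0.645 and 0.734 by edgeR's test. Myog had -0.43 with an adjusted p of 0.226. Myod1 had -0.27 with an adjusted p of 0.105 by edgeR's test, 0.0375 by DESeq2, 0.0234 with length and GC trends removed and 0.0468 with the replicate block and these trends removed. Leaving out single libraries moved the 90 higher genes to 138 without 0 µM replicate 1, to 57, 57 and 49 without 2 µM replicates 2, 3 and 4, and to 52, 53 and 45 without 6 µM replicates 1, 3 and 4. It moved the 88 lower genes to 50, 42 and 33 without 2 µM replicates 2, 3 and 4, and to 41, 40 and 37 without 6 µM replicates 1, 3 and 4.

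The doses were then compared gene by gene. In all, 267 genes were called at both doses against 0 µM in the same direction, 179 higher and 88 lower, and independent lists of these sizes would share 11.8 higher and 4.36 lower. Both comparisons use the same 0 µM libraries, so some overlap arises without PFOS. In 20 simulations of unchanged genes the log2 fold changes of the doses correlated across genes at 0.482 to 0.536, against 0.565 here (genes are not independent replicates). These simulations made at most 1 call per comparison, so they give no value for shared calls. With the 0 µM libraries divided between the comparisons, 2 against 2, the correlation across genes was 0.0672 to 0.106 and 50 to 81 genes were shared. Of these, 36 to 60 were higher and 14 to 30 lower, where independent lists of those sizes would share at most 6.71 higher and 1.93 lower. The 267 shared genes became 160 and 167 without 0 µM replicates 2 and 3, and 166 and 89 without 2 µM replicates 2 and 4. By edgeR no gene was called in opposite directions against 0 µM (0 genes), with 8 such genes at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom.

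A small set of genes turned between the doses, changing at 2 µM against 0 µM and the other way at 6 µM against 2 µM. There were 11 of these, and they were chosen for this pattern after their values were seen. Csf1, Cyr61, Ankrd1, Pnrc2, Gadd45a, Tsc22d3, Ptx3, Nupr1 and Tlk2 rose at 2 µM and fell again, and Txnip and Efna3 fell and rose again. Cyr61 (ENSMUSG00000028195), which encodes a secreted matricellular protein, went from 351.8 ± 17.7 to 472.5 ± 11.98 and then 370.7 ± 23.6 CPM. Its log2 fold changes were 0.42 and -0.35, with adjusted p values of 2.38e-05 and 0.000188 by edgeR's quasi-likelihood test. Leaving out single libraries changed the number of such genes from 11 to 20 and 5 without 0 µM replicates 1 and 2, to 6, 6 and 4 without 2 µM replicates 2, 3 and 4, and to 6, 4 and 6 without 6 µM replicates 1, 3 and 4. Other settings gave 60 with no count filter, 41 by DESeq2, 27 with length and GC trends removed, 21 with only the compared groups, 17 by limma-voom, 17 with the replicate block and these trends removed and 5 with the replicate block.

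The libraries also differed between doses in how many genes they detected. With every library thinned to 30206155 counts, 20557 ± 111 genes had at least 1 count at 0 µM, 20434 ± 299 at 2 µM and 19430 ± 332 at 6 µM (SD, n = 4). For 6 µM against 0 µM the 2-sided exact permutation test gave 0.0286, the smallest p that 70 arrangements allow, or 0.0613 adjusted over 30 tests of 10 library measures. The difference did not pass the adjustment, and as its p was already the smallest possible, a larger difference could not have passed either. Protein-coding genes detected were 14206, 14273 and 13935, and other genes 6351, 6161 and 5495, at 0, 2 and 6 µM. Genes with at least 10 counts were 15040, 14750 and 14612, with the same exact permutation p of 0.0286, or 0.0613 adjusted, for either dose against 0 µM. Gm26917 averaged 1062 ± 146, 1108 ± 81.4 and 1485 ± 66.7 CPM of total counts, with the same exact permutation p of 0.0286 for 6 µM against either dose.

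**Figure D4:**
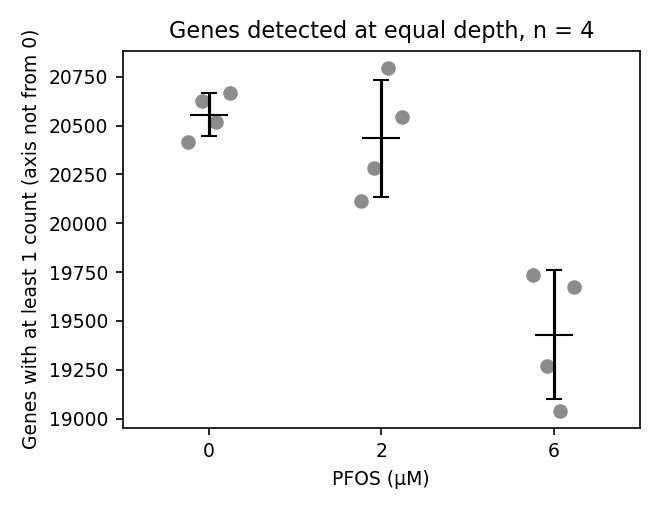
Genes with at least 1 count in each library, thinned to equal depth, by PFOS dose in µM, with means ± SD (n = 4 libraries). The vertical axis does not start at 0, and the means are 20557, 20434 and 19430 at 0, 2 and 6 µM.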

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

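The tests of other groupings of the libraries, of sequencing depth for the genes detected, and of genes turning between the doses were chosen only after the result was seen, and the others before. Each comparison was refitted on all 35 ways to divide its 8 libraries into groups of 4. The real division gave 377 called genes for 2 against 0 µM, where the highest other gave 4, 1322 for 6 against 0 µM, where the highest other gave 1, and 178 for 6 against 2 µM, where the highest other gave 38. In each case 1 of the 35 divisions, the real one, gave as many genes. This treats the 8 libraries as exchangeable. A chance difference shared by the libraries of a dose would also put the real division first, so chance is not excluded.

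Fewer genes were detected at 6 µM than at 0 µM. Depth is argued against as a source, because the difference was -1028 genes with all counts and -1127 genes at equal depth. At equal depth the 4 libraries of each dose did not overlap. Total counts averaged 43.1 M at 6 µM and 36.8 M at 0 µM. Genomic DNA in the 0 µM libraries could add reads to silent genes, and 1740 olfactory and vomeronasal receptor genes together took 10.6 CPM at 0 µM against 7.92 CPM at 6 µM, a ratio of 1.34 with an exact permutation p of 0.0857, which leaves it open. A larger share of unspliced RNA at 0 µM was looked for in unverified (TEC) and sense intronic genes. Their share of counts was 0.077%, 0.0643% and 0.0569% at 0, 2 and 6 µM, a ratio of 1.35 between 0 and 6 µM. These genes are not protein coding, a class whose detected number also fell (6351, 6161 and 5495 at the 3 doses). The share therefore partly restates the pattern and cannot decide its source. At 2 µM the share was already lower, while genes with at least 1 count were close to those at 0 µM (20434 and 20557). Genes with at least 10 counts were fewer at 2 µM (15040, 14750 and 14612 at the 3 doses), so unspliced RNA is left open. RNA quality, library preparation and PFOS itself remain open, since the dose and any handling shared by the libraries of a dose cannot be separated here.

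Sarcomere and contraction genes were lower at 6 µM than at 0 µM by camera with its preset correlation, a call that did not hold with an estimated correlation (adjusted p = 0.0516). A trend with gene length or GC content is argued against as the whole cause, because the list's median log2 fold change was -0.596 with these trends removed and -0.597 before, with a camera adjusted p of 2.11e-12 at the preset correlation. Genes with few reads are argued against as the whole cause, since the 11 members with at least 10 CPM had a median of -0.27 and 5 of them were called. Their fall was smaller than the -0.597 of the whole list, so members with fewer reads added to its size. A single library is argued against, since 10 of the 13 called members kept their call without 0 µM replicate 4, 6 µM replicate 1 or 6 µM replicate 3, the lowest number for any single library. A biological candidate explanation is that fewer cells had begun to differentiate at 6 µM, and this hypothesis was not tested beyond these values. The fewer genes detected, the higher Gm26917 and the lower share of TEC and sense intronic genes at 6 µM remain beside it. So do 4 of 7 adipocyte markers that were higher (camera adjusted p = 0.000171, and adjusted p = 0.0752 with an estimated correlation). Of 9 fibroblast markers, 3 were lower and 1 higher at 6 µM, and that list was not called (camera adjusted p = 0.169).

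A small set of 11 genes turned between 2 and 6 µM, where the middle dose enters both tests. For Cyr61, noise around a steady change with dose is argued against by a p of 0.00244, the larger p of both comparisons by edgeR's test, adjusted over all tested genes. For the other 10 genes, 0 passed that test. Data were also simulated from the observed means, with each 2 µM mean that lay outside the 0 and 6 µM means moved to the nearer of them. These simulations gave 1 to 6 such genes (median 3.5 over 20 simulations) against 11 observed. Noise and a turn therefore cannot be told apart for single genes among the other 10. A single 2 µM library is argued against for Cyr61, which stayed called in both directions without any of them (largest adjusted p 0.00167 by edgeR's test), and is left open for the other 10, of which at least 3 stayed called, while of all 11 genes 7, 5, 5 and 4 stayed without 2 µM replicates 1 to 4 and 5, 8, 4 and 5 without 6 µM replicates 1 to 4, so the loss was not particular to any 2 µM library. For Cyr61 a turn with dose stays a hypothesis, found and tested on the same data.

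Samples far from the others of their dose were searched in 405 groups of 4 libraries, by the gap of the outermost value divided by the range of the group, against Dixon's 95% critical value for 4 samples. There were 21, and chance flags about 1 in 20 groups, which makes 20.2. At 0 µM, replicate 1 stood above the others for Inhba (144.0 against 116.9 to 120.1 CPM, 0.882), for Tiparp (102.4 against 87.9 to 90.3, 0.834) and for Zim1 (33.2 against 29.8 to 30.1, 0.908). At 0 µM, Ces1d was 2.71 CPM in replicate 2 against 3.55 to 3.61 (0.929), and Cd34 was 510.6 in replicate 4 against 526.5 to 529.4 (0.846). At 2 µM, replicate 3 stood apart for Gbe1 (132.7 against 148.2 to 149.8 CPM, 0.906), Gstm2 (56.9 against 60.4 to 60.7, 0.918), Eif4ebp1 (310.4 against 339.2 to 344.8, 0.837), Plin4 (15.6 against 11.4 to 11.9, 0.887) and Spp1 (831.5 against 893.4 to 905.4, 0.838). At 2 µM, Lipe was 4.53 CPM in replicate 2 against 5.84 to 6.11 (0.8293), and Saa3 was 2.02 in replicate 4 against 1.19 to 1.29 (0.872). Mylpf was higher in replicate 1 both at 2 µM (7.03 against 5.89 to 6.01 CPM, 0.895) and at 6 µM (7.195 against 4.97 to 5.28, 0.86). At 6 µM, replicate 3 stood above the others for Slc16a1 (284.4 against 275.3 to 276.2 CPM, 0.901) and Bnip3l (442.6 against 424.8 to 426.9, 0.882), and replicate 2 below them for Ier3 (189.3 against 215.2 to 217.3, 0.925). At 6 µM, replicate 4 was below the others for Ppp1r15a (41.7 against 53.3 to 54.0 CPM, 0.944), Wars (115.5 against 126.1 to 127.9, 0.855) and Igfbp5 (891.5 against 927.4 to 930.1, 0.93), and in total counts (39.8 against 43.9 to 44.7 M, 0.831).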

How the results depend on the processing

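Leaving out the 3 most deviating libraries was chosen only after seeing the data, and the other alternatives before. Of 178 results, 118 were never changed in direction or call. Over the genes named, 3919 combinations of gene and alternative kept their call and direction, 342 lost the call, 5 gained one and 2 reversed, and over the lists that were called 954 kept it, 102 lost it and 0 reversed. Of the 67 list results without a call, 13 gained one in at least 1 of 22 alternatives tested with camera at the preset correlation. Of these, 4 gained it only without a single library, and interferon response genes at 2 against 0 µM with the replicate block (0.0464). Fry was not counted there and called further lists, as given with each comparison. The 2 reversals were Ppara at 6 against 2 µM without 2 µM replicate 3 (0.025) and without 6 µM replicate 1 (0.008), in a range of -0.549 to 0.025 without single libraries beside -0.233 with all, a gene with an adjusted p of 0.932 near the limit of depth. The counts of genes moved as follows, and the cause was not tested where no smaller number of libraries or stricter limit shows it. For 2 against 0 µM, the 258 higher genes became 438 with no count filter, 524 by DESeq2, 430 with length and GC trends removed, 399 with the replicate block and these trends, 64 at an adjusted p under 0.01, 17 at 1.5-fold, and 72 to 322 without single libraries. The 119 lower genes became 193 with no filter, 227 by DESeq2, 201 with the trends removed, 22 at 0.01, 19 at 1.5-fold and 34 to 168 without single libraries. With upper-quartile scaling these were 184 higher and 134 lower. For 6 against 0 µM, the 735 higher and 587 lower genes became 408 and 302 without the 3 libraries, 340 and 245 at 0.01, 54 and 148 at 1.5-fold, and 513 to 789 and 398 to 592 without single libraries. With upper-quartile scaling they were 598 and 662, so more genes fell than rose. For 6 against 2 µM, the 90 higher genes became 177 with no filter, 229 by DESeq2, 174 with only the compared groups, 178 with the trends removed, 140 with block and trends, 42 at 0.01, 12 at 1.5-fold, and 45 to 138 without single libraries. The 88 lower genes became 224, 216, 133 and 133 in the same 4 settings, 54 with the replicate block, 55 without the 3 libraries, 29 at 0.01, 11 at 1.5-fold and 33 to 121 without single libraries. Genes called at both doses, 267, became 408 with no filter, 494 by DESeq2, 455 with the trends removed, 412 with block and trends, 64.5 with divided controls (median of 6) and 89 to 329 without single libraries. The replicate numbers were not found to pair the libraries, with correlations of deviations of -0.028 to 0.037 for the same number and -0.021 to 0.052 for different numbers. With the replicate block as a term, 192 genes rose and 81 fell at 2 µM, 648 and 506 at 6 µM, 69 and 54 between the doses, and 200 were shared. Lists called, 12, 17 and 15 in the 3 comparisons, became 1 in each with an estimated correlation, 10, 22 and 12 by fry, which tests something else, and 10 to 13, 16 to 18 and 12 to 16 without single libraries.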

Other observations

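Some 5 further groups of genes were written as lists after a few of their members had been seen among the called genes of 6 against 0 µM or between the doses, and these members were left out of the tests, whose direction was written down before the other members were looked at. All lists of this part were chosen only after some result was seen, and each is a hypothesis, with camera p values adjusted over the 6 tests of this part. Ribosome biogenesis genes, which build ribosomes in the nucleolus, were higher at 6 µM: of 34 unseen members, 13 rose, among them Utp20, Ddx21, Ncl and Nop2, with a median log2 fold change of 0.17. The adjusted p by camera was 4.86e-13, and adjusted p = 0.0158 with an estimated correlation. Of 14 unseen cytosolic tRNA synthetase genes, 5 rose, among them Rars, Lars and Vars, with a median of 0.12 (camera adjusted p = 2.16e-06, and adjusted p = 0.0204 with an estimated correlation). Both calls held with an estimated correlation when adjusted over the 6 tests of this part. The lists fixed beforehand were adjusted over 111 tests, so the adjusted p values of both parts cannot be compared. These calls are therefore not shown to be firmer than those of the fixed lists. Unseen members were measured in the same libraries as the seen ones, so leaving the seen ones out does not make these tests independent. The integrated stress response list, called higher by camera at 6 µM against 0 µM, also holds cytosolic tRNA synthetase genes such as Wars.

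Mitochondrial proteases and chaperones were prompted by Lonp1, which rose by 0.39, and Hspa9, which rose by 0.32 on the log2 scale at 6 µM against 0 µM. Of 14 unseen members of that group, 3 rose (Lrpprc, Afg3l2 and Trap1), with a median of 0.07 (camera adjusted p = 0.0236, and adjusted p = 0.151 with an estimated correlation). Imprinted genes were prompted by H19 and Peg3, which fell by 0.57 and by 0.42 on the log2 scale at 6 µM. Of 11 other imprinted genes, 1 fell (Impact), and the group was not called (camera adjusted p = 0.398, and adjusted p = 0.446 with an estimated correlation). A list that was not called cannot show whether the falls of H19 and Peg3 stand alone.

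Cyr61 and Ankrd1, which rose at 2 µM and fell again at 6 µM, are known targets of the YAP coactivator, so a turn of YAP targets with dose was tested as a hypothesis on 19 other targets. At 2 µM against 0 µM, 2 rose and 1 fell with a median of 0.08 (camera adjusted p = 0.0236, and adjusted p = 0.255 with an estimated correlation). At 6 µM against 2 µM, 2 fell with a median of -0.05 (camera adjusted p = 0.0236, and adjusted p = 0.255 with an estimated correlation). Both comparisons use the 2 µM libraries, so a deviation of these libraries alone would give opposite directions, and the pair is not counted as separate evidence. Neither call held with an estimated correlation, and a turn of YAP targets stays open.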
